A study of Pseudoalteromonas sp. A2 with 2 samples.

How the data were processed

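RNA was extracted from cultures of Pseudoalteromonas sp. A2 with TRIzol, and libraries were made from 5 µg of total RNA with the TruSeq RNA kit, per the labels' protocols. Cultures grew at 10 °C and 150 r/min in ZoBell 2216E medium (5 g tryptone and 1 g yeast extract per litre of seawater). The labels describe 1 sample without H2O2 (control) and 1 with 1 mmol/L H2O2, and each title names a pair of preparations; whether their reads or their values were merged is not given in the sources used here. The authors deposited FPKM values with 1 column per group, and an annotation table with the length of each protein in amino acids, descriptions from protein databases and KEGG symbols. Bowtie2 is named in the submitters' processing notes, with no version; the reference, the counting tool and the use of strand are not given in the sources used here. All 3703 gene identifiers of the deposited FPKM table matched the annotation after a suffix was removed, 3680 with a description and 2092 with a KEGG symbol. The sums were 1017460 FPKM (control) and 1077770 FPKM (H2O2), and 19 and 24 genes were listed at 0.

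No total count was used, so depth was recovered from low values, which are whole multiples of the value of 1 fragment. A single length offset (-24 nucleotides on 3 times the protein length) and 1 depth per library were chosen to make the most values of under 15 fragments whole within 0.1, over proteins of at least 50 amino acids. The share of whole values, taken over all genes, was 90.6% of 138 values in the control library and 89.8% of 128 in the H2O2 library. By chance 20% would be whole at a depth not chosen for that share. The offset and depths were chosen for it, so the chance level of the chosen values is higher and was not measured. The fitted depths were 4502500 and 5205000 fragments, and the fragments recovered for all genes summed to 4456352 and 5174725. These sums do not check the depths, since each recovered value is proportional to the fitted depth. Intervals at 95% come from these fragments, rounded: exact conditional binomial (Clopper-Pearson) for folds. Fragments are not independent molecules, so the intervals cover counting error only.

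The change of a gene was log2(FPKM + 1) with H2O2 minus that of the control, with no rescaling. Genes with a mean of at least 10 FPKM were counted as higher or lower at 2-fold. With 1 sample per group no test was made and no p-value is given. For 32 gene lists, written as text patterns on one product description and the symbol, the median change was placed among the medians of 10000 random lists of the same size drawn within 10 bins of mean expression, for the 30 lists with at least 3 measured genes. A list was called high or low beyond the percentiles 97.5 and 2.5. The lists, the thresholds and the rule for named genes were fixed before the data were examined. The rule took the 12 largest increases and 12 largest decreases among described genes, all measured genes (at most 10, by mean FPKM) of the peroxide, superoxide, regulator and iron storage lists, the 2 largest changes of each other list called high or low, and the 5 genes with the highest mean, which gave 65 genes.

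The steps were tested on simulated data for the comparison of H2O2 with control: fragments of 3703 genes were drawn from Poisson counts, with 200 genes changed. The offset was found as -25 for a given -24, and depths within 0.298% and 0.402%. Of the genes changed 2.5-fold, 98% were found at least 2-fold apart in the right direction, and 100% of those changed 4-fold, with 6 of 3307 unchanged genes past 2-fold. Of 200 random lists with no shift, 3% stood beyond either percentile. The simulation held counting error only, with each gene drawn independently of its neighbours. It therefore does not give the rate of false calls for the real lists or between real cultures. Alternatives tried were pseudocounts of 0.1 and 10, centring on the median, scaling to the same summed FPKM, no minimum and a minimum of 50, a 4-fold threshold and unmatched random lists. Chosen after seeing the data were lists searched in all description text, lists without genes caught by an accident of the text, lists rotated along the gene order, the flagellar list with all lateral flagellar genes, and 1 gene per set of identical copies. No gene or sample was left out other than by the minimum. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.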

Results

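RNA of Pseudoalteromonas sp. A2, an Arctic bacterium isolated from seawater, was sequenced from cultures grown at 10 °C without hydrogen peroxide (H2O2) or with 1 mmol/L H2O2. Each group had 1 sample, so there are no replicates, and every difference below is a difference between these 2 libraries. The tables listed 3703 genes in FPKM, fragments scaled to gene length and to library depth, with a median of 85.7 FPKM in the control library and 80.4 FPKM in the H2O2 library. The depth recovered from the steps of low values was 4502500 fragments for the control library and 5205000 for the H2O2 library, with medians of 317 and 335 fragments per gene. Genes are named by the symbol and the number that the tables give them, since no genome coordinates were used here. Each fold is the ratio of the 2 FPKM values, and the range after it is its 95% interval for counting error only. A change is the difference of log2(FPKM + 1), H2O2 minus control, which understates the change of low genes.

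The comparison asked which genes differed in level when the bacterium was exposed to oxidative stress. In the H2O2 library, astA and astD of arginine breakdown, a stretch of lateral flagellar genes, and the lists of chaperones and of thioredoxins were higher, and arginine synthesis genes, coxB and coxC of a cytochrome c oxidase and a secreted protease were lower. A TonB-dependent receptor (orf02113), an outer membrane protein of a family that takes up large nutrients, stood at 28.2 FPKM in the control library and 7519 FPKM in the H2O2 library, 266-fold higher (240 to 297). At the other end, argB (orf02907), which encodes acetylglutamate kinase of arginine synthesis, was 228-fold lower (148 to 367), at 1235 FPKM against 5.41 FPKM. Among the 3511 genes with a mean of at least 10 FPKM, 326 were at least 2-fold higher with H2O2 and 425 at least 2-fold lower, and 2760 lay within 2-fold. At least 4-fold, the numbers were 106 higher and 171 lower. The counting interval of the fold excluded 1 for 325 of the 326 higher genes and 416 of the 425 lower genes, so the depth was enough to tell these libraries apart, which is no test of the conditions. The median change of all 3511 genes was -0.00, and their SD was 1.15.

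**Figure D1:**
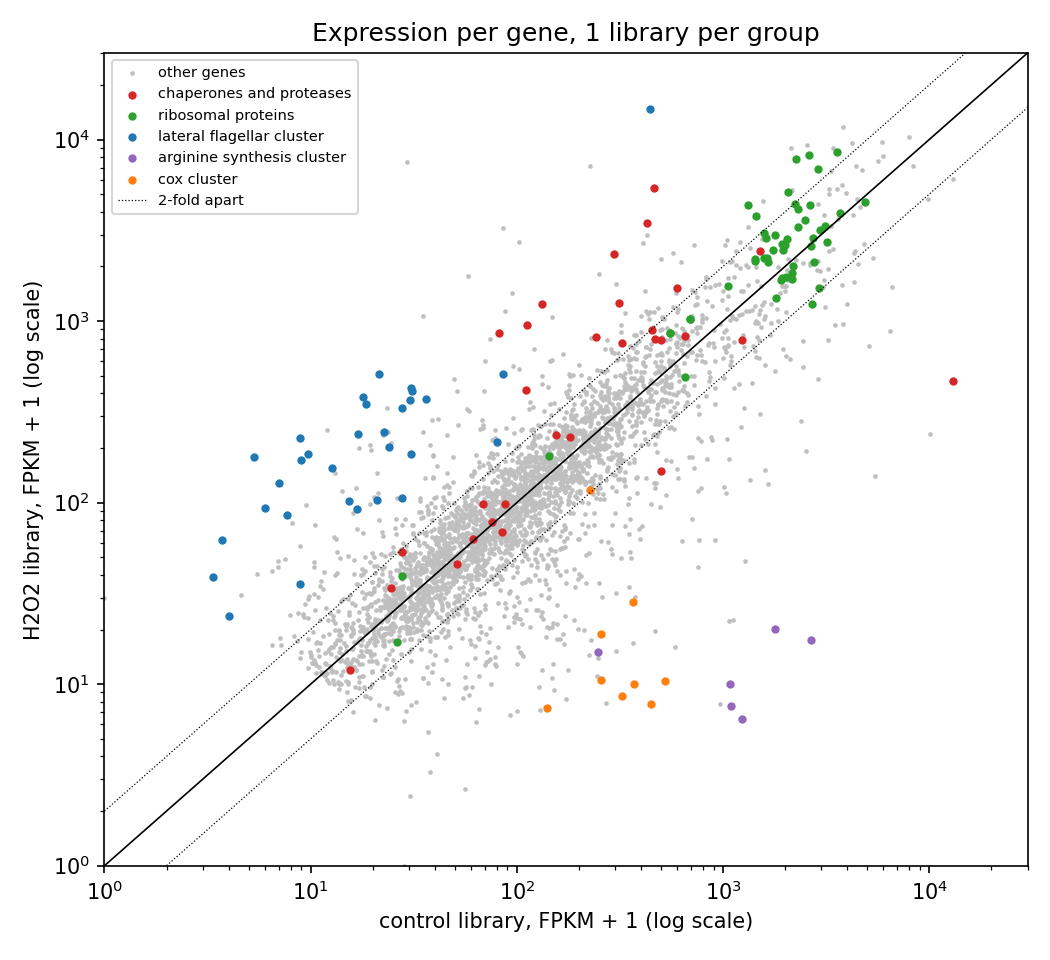
FPKM + 1 of each of the 3511 genes with a mean of at least 10 FPKM, control library on the x axis and H2O2 library on the y axis, both on log scales, 1 point per gene; the solid line marks equal values and the dotted lines 2-fold. The lateral flagellar genes (blue) lie above the upper line and the arginine synthesis genes (purple) far below the lower one; the lateral flagellar, arginine and cox (orange) groups were picked after the values were seen.

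Genes of the known peroxide defences went both ways. The list of 19 peroxide scavenging genes had 2 members at least 2-fold higher, 6 at least 2-fold lower and 11 within 2-fold; beyond counting error, 5 were higher and 9 lower. Its most abundant member, a thioredoxin peroxidase of the ahpC family (orf00193), was 3.66-fold higher (3.56 to 3.76), at 2566 against 9390 FPKM, and a glutathione peroxidase (orf03265) was 2.06-fold higher (1.73 to 2.47), with a change of 0.95, under 2-fold, when both libraries were scaled to the same summed FPKM. The catalase-peroxidase katG (orf01333) was 1.44-fold lower (1.38 to 1.501), and an organic hydroperoxide resistance gene (orf01211) was 2.36-fold lower (1.93 to 2.88). The list also held orf03679, 2.96-fold lower (2.74 to 3.20), described as a cytochrome c peroxidase but with the symbol of a heavy metal efflux protein and a length of 1050 amino acids, so its place among peroxide defences is uncertain. Picked after the values were seen, a second katG (orf02526) and another ahpC (orf01086) were 4.57-fold lower (3.95 to 5.31) and 5.16-fold lower (3.85 to 6.96), and a glutathione peroxidase (orf03473) and the catalase katE (orf01871) were 1.49-fold (1.20 to 1.85) and 1.35-fold higher (1.02 to 1.79). The thiol peroxidase tpx (orf00558), at 244 and 241 FPKM, and an OsmC gene (orf00959), at 275 and 284 FPKM, did not differ beyond counting error. The peroxiredoxin genes bcp (orf00480) and orf00114 were 2.23-fold (1.82 to 2.75) and 1.88-fold lower (1.73 to 2.06), and orf02706 was 1.32-fold higher (1.19 to 1.47). The list's median change was -0.20, at the 15.02th percentile of 10000 random lists matched on expression; with a minimum of 50 FPKM it stood at the 1.05th percentile over 15 genes, and without orf03679 at the 29.9th over 18 genes. The percentile describes these libraries only.

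The iron superoxide dismutase (orf00565), which converts superoxide to H2O2 and oxygen, was 2.42-fold higher (2.28 to 2.57), at 593 against 1436 FPKM. Of the redox and iron regulators, soxR (orf01158) was 2.03-fold higher (1.75 to 2.36; change 0.93, under 2-fold, at the same summed FPKM), fur (orf00751), the ferric uptake regulator, 1.94-fold lower (1.74 to 2.17), and iscR (orf01746) 1.60-fold lower (1.27 to 2.04). One gene annotated oxyR (orf00115) was 1.68-fold higher (1.37 to 2.06) and another (orf02804) was 1.26-fold lower (1.06 to 1.48); the ohrR gene (orf01212), at 33.5 against 26.8 FPKM, did not differ beyond counting error. The list of 9 had 1 member at least 2-fold higher and a median of -0.32, at the 12.6th percentile; its text pattern also caught xseA (orf00007), phrB (orf00900) and endA (orf01463), which act on DNA. Of the 5 genes matched by the iron storage pattern, bfd (orf01057) was 3.42-fold lower (3.07 to 3.80). It is described as a bacterioferritin-associated ferredoxin and not as a storage protein. Both bfr genes (orf01054 and orf01055) were 1.39-fold (1.25 to 1.55) and 1.52-fold lower (1.37 to 1.68), and dps (orf03293), a DNA-binding iron storage protein, was 1.88-fold higher (1.75 to 2.01). A gene with the symbol dps but the description of a DNA polymerase clamp (orf02533) stood at 22.3 FPKM in both libraries. The list's median was -0.48, at the 10.9th percentile.

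Thiol redox genes and chaperones stood apart from random lists, at the high end. Of 29 genes of the thioredoxin and glutathione systems, 8 were at least 2-fold higher, 2 at least 2-fold lower and 19 within 2-fold, with a median of 0.40 at the 99.4th percentile. Beyond counting error, 18 were higher and 8 lower, with the largest decrease at bcp (orf00480), named above. The thioredoxin-like ybbN (orf02008) was 9.82-fold higher (8.42 to 11.5) and a glutathione S-transferase (orf01272) 8.22-fold higher (6.86 to 9.87). Picked after the values were seen, the thioredoxin reductase trxB (orf02206) was 7.30-fold higher (6.84 to 7.79) and thioredoxin trxA (orf03530) 4.38-fold higher (4.04 to 4.77). Of 30 chaperone and protease genes, 11 were at least 2-fold higher, 2 lower and 17 within 2-fold, with a median of 0.67 at the 99.97th percentile. Without 3 genes caught by an accident of the text, the median of 27 genes was 0.69, also at the 99.97th percentile. The chaperone dnaK (orf00994) was 11.7-fold higher (11.3 to 12.1), at 462 against 5403 FPKM, and groEL (orf02858), hslV (orf01625) and htpG (orf00556), picked after the values were seen, were 8.12-fold (7.83 to 8.43), 10.5-fold (9.03 to 12.3) and 8.58-fold higher (8.02 to 9.18). The list also held cspA (orf02199), a cold shock RNA chaperone, which was 27.95-fold lower (25.5 to 30.7), at 13030 against 466 FPKM. The 4 cold shock genes had 1 member at least 2-fold lower and a median of -0.47, at the 14.3th percentile, and another cspA (orf00538) stood at 8018 and 10380 FPKM. The 38 genes of the SOS response and DNA repair had 6 members at least 2-fold higher and 1 lower, with a median of 0.13 at the 89.1th percentile.

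Ribosomal protein genes were higher as a list, and ATP synthase genes lower. Of 51 ribosomal protein genes, 7 were at least 2-fold higher, 1 lower and 43 within 2-fold, with a median of 0.48 at the 98.1th percentile. The ribosomal protein genes rplP (orf01500) and rpsC (orf01499) were 3.44-fold (3.32 to 3.57) and 3.30-fold higher (3.19 to 3.42). Along the S10 stretch of ribosomal genes the change ran from -1.12 at rpsJ to 1.25 at rpmC, and the ribosome modulation factor gene rmf (orf02399), picked after the values were seen, was 13.3-fold lower (11.2 to 15.9). All 3 members at least 2-fold apart among the 9 ATP synthase genes were lower, with a median of -0.85 at the 1.28th percentile; atpB (orf03548) and atpE (orf03547), subunits of its membrane part, were 2.81-fold (2.69 to 2.93) and 2.38-fold lower (2.24 to 2.51). That percentile was 5.41 when the list was moved along the gene order, which keeps neighbours together, so the call did not hold there. Of the 4 genes in the glyoxylate shunt list, 3 were at least 2-fold lower, with a median of -1.84 at the 0.450th percentile. However, the text pattern caught 2 of the 4 from other pathways, prpB (orf02178), a methylisocitrate lyase of propionate use, 10.2-fold lower (9.38 to 11.2), and leuA (orf03360) of leucine synthesis, at 11.2 against 14.2 FPKM. Without them 2 genes are left, too few for a percentile, so the call ends: the isocitrate lyase aceA (orf01359) was 4.71-fold lower (4.47 to 4.96) and the malate synthase aceB (orf01360) 2.74-fold lower (2.53 to 2.98). The genes leuA and aceB were named after their values were seen. The TCA cycle list had 5 of 22 members at least 2-fold lower and 2 higher, at the 4.82th percentile (median -0.29). Without 3 genes caught by an accident of the text, it stood at the 7.1th percentile over 19 genes (median -0.27). The respiratory chain list had 6 of 28 lower and 5 higher, at the 3.74th percentile (median -0.28). The cytochrome c oxidase genes coxB (orf03376, described as a cytochrome b559 subunit in one of the annotations) and coxC (orf03379) were 65.1-fold (46.9 to 91.6) and 55.1-fold lower (40.3 to 76.1), and the assembly gene COX11 (orf03378) 42.5-fold lower (27.2 to 69.6). The text pattern of the respiratory chain list missed coxB and, picked after the values were seen, coxA (orf03377), 41.2-fold lower (32.9 to 53.1). With all description text, an alternative chosen after seeing the data, that list stood at the 1.32th percentile over 32 genes.

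Arginine synthesis genes were among the lowest genes of the H2O2 library relative to the control, and astA and astD of arginine breakdown among the highest. Of the 13 genes of histidine and arginine synthesis, 8 were at least 2-fold lower, 1 higher and 4 within 2-fold, with a median of -1.18 at the 0.0300th percentile. Beside argB, argG (orf02909), argC (orf02906), argF (orf02908) and argHA (orf02910) were 161-fold (133 to 198), 167-fold (119 to 240), 120-fold (87.9 to 164) and 93.3-fold lower (80.9 to 109). The text pattern of the list did not match argC, so argC is not among the 13. The single higher member, argD (orf01546), described as a bifunctional acetylornithine and succinyldiaminopimelate aminotransferase, was 38.1-fold higher (34.7 to 42.0) and lies next to astA (orf01547) and astD (orf01548) in the gene order, which were 31.3-fold (27.6 to 35.6) and 26.7-fold higher (24.7 to 28.9). The ast genes encode arginine breakdown through succinylated intermediates. An agmatinase gene, speB (orf01024), was 31.2-fold higher (26.7 to 36.6). Also far lower with H2O2 were the secreted metalloprotease Mcp02 (orf00859), 142-fold lower (114 to 181), prpE (orf02518), 50.3-fold lower (43.9 to 58.1), an aldehyde dehydrogenase (orf01129), 42.8-fold lower (40.8 to 44.8), and the symporter actP (orf02492), 39.0-fold lower (36.8 to 41.3).

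Flagellar genes went both ways. The list of 126 flagellar and chemotaxis genes had 20 members at least 2-fold higher, 22 at least 2-fold lower and 84 within 2-fold, with a median of -0.24 at the 0.0700th percentile and a mean of -0.04. Its text pattern missed 14 of the 32 lateral flagellar genes, described as hypothetical or under other names; with them, an alternative chosen after seeing the data, the median of 140 genes was -0.14, at the 2.23th percentile. The flagellin gene fliC (orf03005), in a stretch with genes described as lateral flagellar, was 33.6-fold higher (32.002 to 35.3), at 441 against 14825 FPKM, the highest value of the H2O2 library. In the same stretch of genes, fliN (orf03016) was 41.0-fold higher (18.5 to 112), flgH (orf02999) 28.6-fold (19.2 to 44.5), flgK (orf03002) 24.9-fold (20.7 to 30.1), flgG (orf02998) 22.4-fold (17.2 to 29.6) and flgJ (orf03001) 21.4-fold higher (13.2 to 37.0). Of the 32 genes of this stretch, a set picked after the values were seen, 31 were at least 2-fold higher, with a median of 3.60, and flgA (orf02992), under the minimum, stood at 7.84 against 11.9 FPKM, 1.52-fold (0.926 to 2.58), whereas of 37 genes in the polar flagellar stretches 0 were at least 2-fold higher and 2 were lower, with a median of -0.20. The chemotaxis regulator gene cheY (orf03386) was 39.5-fold lower (22.3 to 76.9), in a second chemotaxis stretch whose 7 genes were all at least 2-fold lower.

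**Figure D2:**
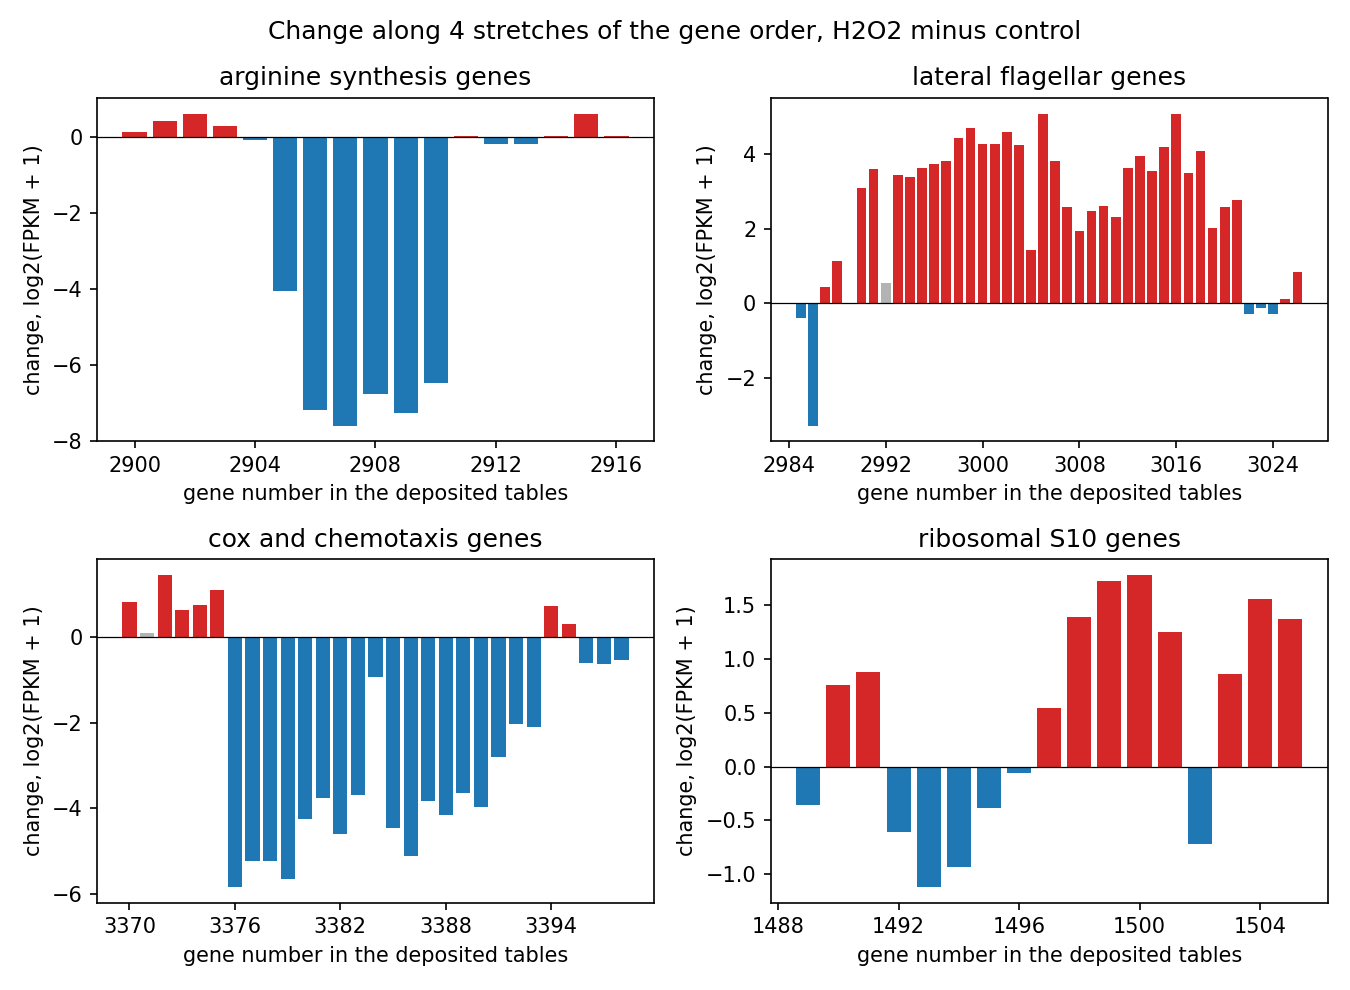
Change in log2(FPKM + 1), H2O2 minus control, on the y axis for 4 stretches of genes numbered as in the deposited tables on the x axis; red bars are higher with H2O2, blue bars lower, and grey bars mark genes with a mean under 10 FPKM. The 6 arginine synthesis genes reach a change of -7.59 (argB, orf02907), while the lateral flagellar stretch reaches 5.07 (orf03005); the stretches were picked after the values were seen.

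Of the 45 TonB uptake and siderophore genes, 5 were at least 2-fold higher and 12 lower, with a median of -0.20 at the 4.34th percentile. The most abundant receptor of the control library (orf00356) was 2.15-fold lower (2.14 to 2.17), at 13097 against 6080 FPKM, while another receptor (orf01154) was 22.7-fold higher (18.8 to 27.7). Other abundant genes were the outer membrane gene ompW (orf03084), 3.06-fold higher (2.99 to 3.12), the DNA-binding protein gene hupB (orf00891), 1.63-fold higher (1.59 to 1.68), and hcp (orf01184), 1.16-fold lower (1.14 to 1.19). The lists that follow stood within the middle 95% of random lists. Medians were -0.01 for 8 Fe-S cluster assembly genes, 0.34 for 23 translation factors, 0.06 for 22 aminoacyl-tRNA synthetases, 0.23 for 20 genes of glycolysis and the pentose phosphate pathway, 0.07 for 13 fatty acid degradation genes and 0.69 for 8 fatty acid synthesis genes. They were -0.17 for 28 genes of type IV pili and type II secretion, 0.03 for 10 sulfur assimilation genes, 0.03 for 11 branched-chain amino acid genes, 0.24 for 18 purine and pyrimidine genes and -0.05 for 87 peptidases. They were -0.22 for 28 efflux genes, -0.03 for 19 RNA polymerase and sigma factor genes, 0.13 for 60 cell division and peptidoglycan genes and -0.19 for 48 phage and transposase genes. Without 3 genes caught by an accident of the text, the RNA polymerase and sigma factor median turned to 0.33, at the 89.3th percentile. Of the 60 cell division genes, 30 were such accidents, and the other 30 had a median of 0.31 at the 98.4th percentile, past the limit. With both libraries scaled to the same summed FPKM, the medians of aminoacyl-tRNA synthetases, fatty acid degradation, sulfur assimilation and branched-chain amino acid genes changed sign. The mean had the other sign from the median for Fe-S cluster assembly (0.05), glycolysis and pentose phosphate (-0.10), fatty acid degradation (-0.52), RNA polymerase and sigma factors (0.15) and cell division (-0.18). The structural RNA pattern caught 2 protein genes of tRNA modification and no RNA gene, both within 2-fold.

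**Figure D3:**
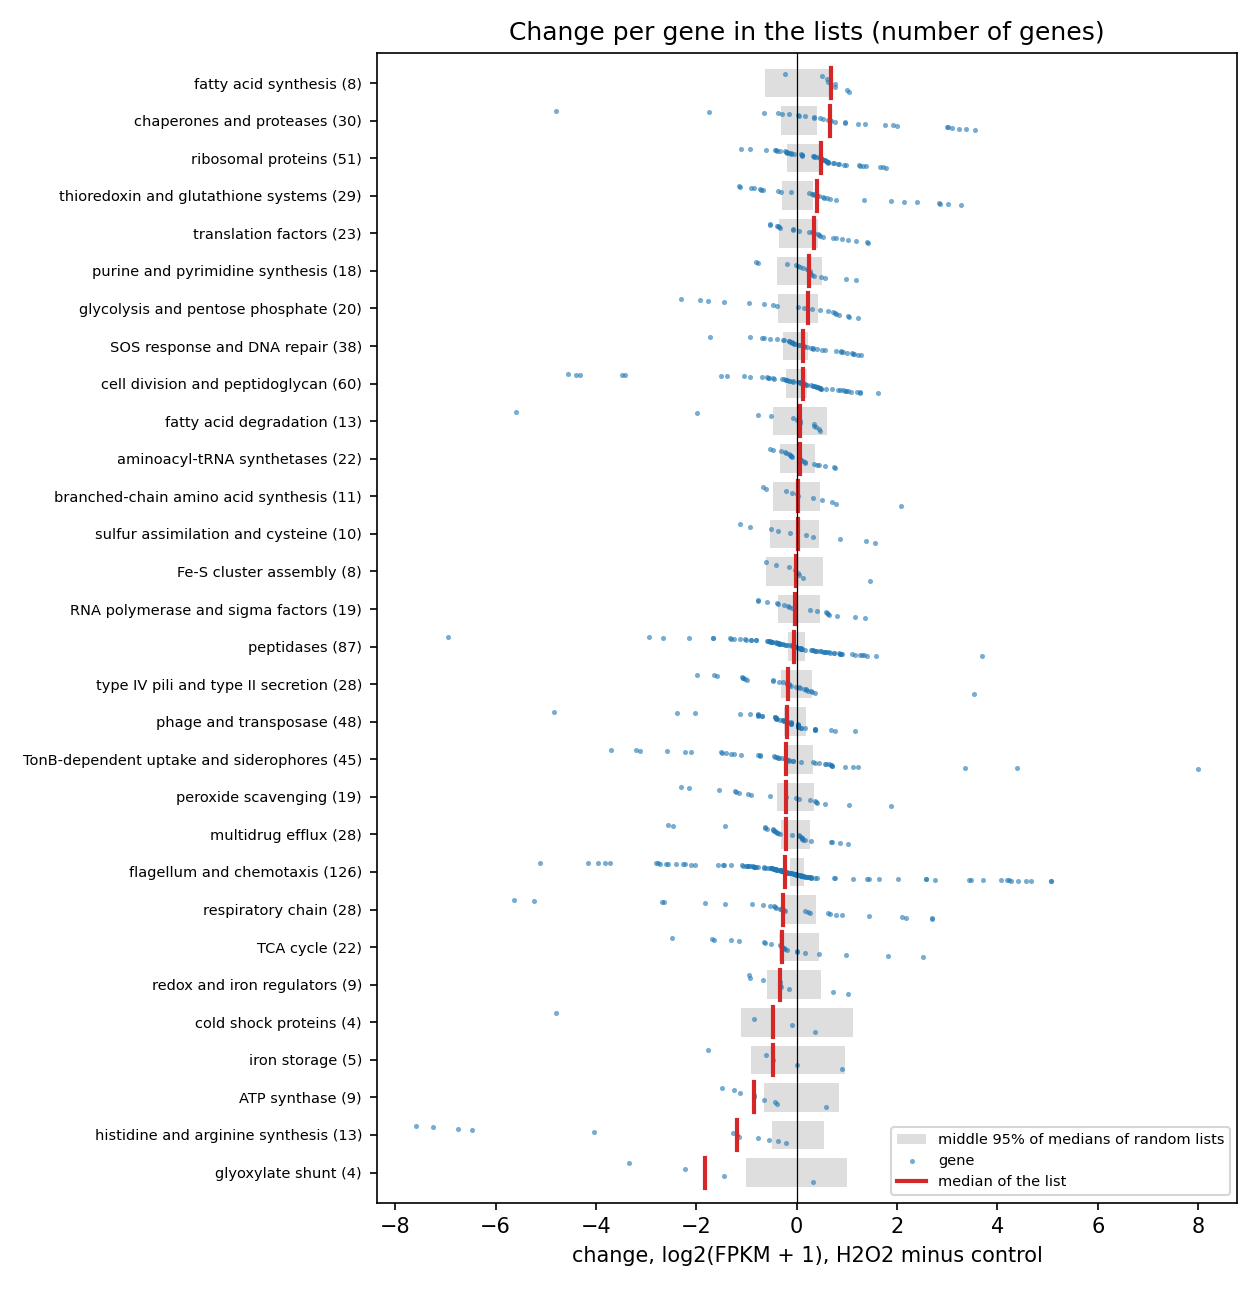
Change in log2(FPKM + 1), H2O2 minus control, on the x axis for each gene (blue points) of the 30 lists with at least 3 genes, 1 list per row with its number of genes; red marks are list medians and grey bands hold the middle 95% of the medians of 10000 random lists. Of these lists, 7 have a median outside the band, 3 above and 4 below, against 1.5 by chance if genes were independent, which neighbours are not: 6 of the 7 calls held with lists moved along the gene order, and the glyoxylate shunt call ends without its text accidents.

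The difference of each gene has no replicate check, and the length of exposure and the stage of growth are not given in the sources used here. For the 67 of 3511 genes with copies of identical values and length the value of each copy is uncertain, as is that of overlapping genes, since the strand used in counting is not given in the sources used here.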

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

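The lists searched in all description text, freed of text accidents, given all lateral flagellar genes or rotated along the gene order, and the use of 1 gene per set of copies, were alternatives chosen after seeing the data; the others were planned. Over the settings that kept the 2-fold threshold, between 245 and 339 genes were higher and between 308 and 474 lower, with more lower than higher genes in each. The lowest counts came with the minimum of 50 FPKM, which kept 2483 genes. Of these, 9.87% were higher and 12.4% lower, against 9.29% and 12.1% of the 3511 genes of the main setting. At a threshold of 4-fold the counts were 106 and 171, as a stricter threshold must lower them. For lists, 320 percentiles stayed on their side of the limits, 9 passed a limit and 1 lost its call, and no call turned. The 320 include percentiles that could not move. Centring shifts a list and its random lists alike, and many lists had no text accidents to leave out. The RNA polymerase median turned from -0.03 to 0.33 without text accidents, and that of Fe-S cluster assembly from -0.01 to 0.01 with a minimum of 50 FPKM. The ATP synthase list stood at the 5.41th percentile when rotated along the gene order, which keeps neighbouring genes together, and so lost its call. With a minimum of 50 FPKM the peroxide scavenging list stood at the 1.05th percentile, and with no minimum the TonB list at 0.98; with a pseudocount of 10 the respiratory chain list stood at 2.37. With random lists not matched on expression, translation factors stood at 97.9 and fatty acid synthesis at 99.2. With all description text, the TonB list stood at 1.55, the respiratory chain at 1.32 and phage and transposase at 1.88. Without text accidents the cell division list, from which 30 of 60 genes were left out because a word ending in -mine matched the pattern, stood at 98.4; for all of these but the threshold the cause was not tested. Without text accidents the glyoxylate shunt list had too few genes for a percentile. Of the values of named genes under other settings, 220 stayed within their counting interval and 40 moved past it. All 45 at least 2-fold apart kept their direction, which was fixed in advance. An equal pseudocount cannot turn a sign, and the shifts from centring and scaling are far smaller than 2-fold. At the same summed FPKM 43 of these 45 stayed past 2-fold, as orf03265 had a change of 0.95 and soxR (orf01158) of 0.93 (0.97 with a pseudocount of 10), and orf00959 turned from 0.05 to -0.04. The planned use of the first or second preparation alone was not run, since the tables have 1 column per group, and lists on COG descriptions were not run, since no such description was used here. No paired analysis was possible because each group has 1 sample. Depth limits the size of a fold where a library gave few fragments, as for fliN (orf03016), with an interval of 18.5 to 112.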

Other observations

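The gene sets and runs of neighbouring genes described here, and the tests of explanations for the lateral flagellar, S10 and ATP synthase, and ribosomal patterns, were chosen after the values were seen; the list of ribosomal proteins was fixed before. A run of 8 neighbouring genes (orf00915 to orf00922) was lower in the H2O2 library, with a median change of -1.71, among them glgC (orf00916), which makes the glucose donor of glycogen synthesis, 4.55-fold lower (4.11 to 5.05), and the phosphorylase glgP (orf00917), 5.66-fold lower (5.21 to 6.16). The 4 neighbouring genes thiC, thiO, thiS and thiG of thiamine synthesis were all at least 2-fold lower, with thiC (orf01695) 24.8-fold lower (21.5 to 29.0) and thiO (orf01696) 23.7-fold lower (16.9 to 33.7). In a set of 5 genes of the methylcitrate cycle of propionate use, all were at least 2-fold lower, among them prpC (orf02179), 10.6-fold (9.92 to 11.4), and the ethanolamine lyase genes eutB (orf01296) and eutC (orf01295) were 11.2-fold (9.34 to 13.5) and 12.1-fold lower (8.93 to 16.4).

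The 4 cyo genes of a cytochrome o ubiquinol oxidase were all at least 2-fold higher, with a median of 2.43, among them cyoB (orf02968), 7.13-fold higher (5.55 to 9.26) from 7.91 FPKM. The cytochrome bd oxidase genes cydA (orf00310) and cydB (orf00309) were 3.58-fold (3.39 to 3.77) and 6.51-fold lower (6.002 to 7.06), and of 9 genes in the cox stretch 8 were at least 2-fold lower. The 3 measured cbb3 oxidase genes and 6 nqr genes of a sodium-pumping NADH reductase stayed within 2-fold. A run of 7 genes with the symbols of type VI secretion genes (orf01185 to orf01191) was higher, with a median of 1.40, and impF (orf01188) was 4.20-fold higher (3.10 to 5.77). The abundant gene hcp (orf01184), next to this run in the gene order, was not higher but 1.16-fold lower (1.14 to 1.19). Of 27 measured methyl-accepting chemotaxis proteins, 11 were at least 2-fold lower and 2 higher. In all, 16 runs of at least 5 neighbouring genes were at least 2-fold apart in 1 direction, 4 higher and 12 lower, with 126 genes.

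Of 32 lateral flagellar genes, 31 were at least 2-fold higher with H2O2. Reads shared with the polar copies are argued against by 27 polar genes with the same symbols, whose median change was -0.199 and whose highest was 0.29. Few fragments in the control library are argued against too, since 31 of all 32 lateral genes, taken with no minimum, had a lower counting bound above 2-fold; flgA (orf02992), 1.52-fold (0.926 to 2.58), did not. As a hypothesis, the lateral system may have responded to H2O2; a difference between the cultures other than H2O2 stays open, as each group has 1 sample.

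The change rose along the S10 ribosomal stretch, by 0.757 per kb (SE 0.0899 across genes), and along the ATP synthase stretch, by 0.186 per kb (SE 0.0236); these genes are not independent replicates. One 3' bias in all transcripts of a library is argued against as the whole cause, since 5 of 12 other clusters had a slope plus 2 SE under the lower bounds of both. Both stretches were picked for their rise, which favours such an outcome and weakens the argument. As 8 of the 12 others rose too, isc by 0.216 and his by 0.175 per kb, a 3' bias that differs between transcripts stays open. Gene length bias between the libraries is argued against as well, since in all 11 pairs of genes in these stretches with lengths within 20% of each other the downstream gene had the higher change, by a median of 1.06. In the ATP synthase stretch the differences were smaller, from 0.417 to 0.838. The pairs share genes and come from stretches picked for their rise, so their number is no measure of certainty. With the trend on length over all measured genes taken out, the slopes were 0.749 (S10) and 0.194 (ATP synthase) per kb. A candidate explanation, as a hypothesis, is that initiation of transcription changed shortly before sampling. The Spearman correlation of slope with mean FPKM over 14 clusters was 0.235. This fell short of the correlation that the explanation predicted but did not reach the limit set against it, so it decides nothing. With no time course this explanation cannot be told apart from other causes.

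Ribosomal protein genes were higher as a list, with 15 of 51 lower, while the ribosome modulation factor gene rmf (orf02399), which acts on ribosomes of resting cells, was lower, at 2539 against 191 FPKM. Cultures sampled at different stages of growth could give such a pattern. Of 11 genes matched by a text pattern for stationary phase markers other than rmf, 5 were higher with H2O2 and 2 lower beyond counting error. The other 4 did not differ beyond it, and the median of all 11 was 0.370. The 2 lower genes were rpoS (orf00050), 1.72-fold (1.63 to 1.82), and a gene described as CstA-like (orf01140), 3.83-fold (3.63 to 4.04). The CstA-like gene was the single member at least 2-fold apart, and 0 were at least 2-fold higher. The higher genes included dps (orf03293) and the catalase katE (orf01871), named above with iron storage and peroxide defence, so these 2 cannot separate growth stage from H2O2. Not named above with those defences were bolA (orf02956), 1.44-fold higher (1.21 to 1.73), and sspA (orf01799), 1.30-fold higher (1.23 to 1.38). A relA gene (orf03629) was also among the higher genes, a symbol shared by another of the 11. With members on both sides and no cell density given, growth stage and H2O2 cannot be told apart here.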
